A study of Homo sapiens with 12 samples.

How the data were processed

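The data were 12 arrays of the MDA231 cell line, 3 each for scramble, scramble with ETX, shCPT-1 and shCPT-2, made per the labels from total RNA with a biotin label on single-colour Affymetrix arrays. The deposited values are 1 intensity per probe set and array on a linear scale, from 6.68 to 28791, made with RMA (background correction, normalization between arrays and summary of probes) per the submitters' processing notes. The software version, its settings and a genome build are not given in the sources used here. Every column was mapped to a labelled array. The labels name no batch and pair no replicates. The labels give CPT1 without an isoform.

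There were 54675 probe sets, of which 62 were controls. By the gene names used here, 41091 of the other probe sets had 1 gene symbol, 1801 had several and 11721 had none. Log2 intensities were used. A probe set was kept when it exceeded its array's median on at least 3 arrays, which kept 28630 probe sets, 23565 of them with 1 symbol. Of several kept probe sets of a gene the one with the highest mean over all arrays stood for the gene, which gave 12887 tested genes, 6173 of them with several kept probe sets. For arrays, depth is signal over background, and the filter left out genes above the median on fewer than 3 arrays. A kept gene may still lie under the array medians in a group, where its fold is less certain, as GDF15 did in scramble, VNN1 in both knockdowns and TRIM22 in shCPT-2.

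Groups were compared with limma 3.58.1 (lmFit and eBayes, no covariates, 8 residual and 4.117 prior degrees of freedom) in R 4.3.3 with data.table (version 1.17.8), using all 12 arrays for the spread. Tests were two-sided, and a gene was called at a Benjamini-Hochberg adjusted p under 0.05 within its comparison. An exact test of 3 arrays against 3 cannot go below p = 0.1, so none was used for single genes. The 4 groups were compared with the moderated F test. Figures were drawn with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.

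The 30 gene lists, written from general knowledge, name 820 genes, of which 682 had a tested value. They cover beta-oxidation, PPAR targets, fatty acid and cholesterol synthesis, glycolysis, oxidative phosphorylation, the TCA cycle, mitochondrial biogenesis, Src kinases, ATF4, ER and NRF2 stress, DNA replication and mitosis. They also cover interferon, NF-kB, mesenchymal, epithelial, invasion, hypoxia, immediate early, YAP, p53, lysosome, ribosome and proteasome genes, and markers of leukocytes, endothelium, fibroblasts and luminal epithelium. Some genes are on several lists. The targeted genes were not taken out: CPT1A is on the beta-oxidation and PPAR lists and CPT2 on the beta-oxidation list, also in the knockdown of that gene. Lists were tested with limma's camera at a preset inter-gene correlation of 0.01, with the estimated correlation beside it, and with fry, which tests whether a list's genes move one way without comparing them with other genes.

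The comparisons, the filter, the lists, the alternatives and the rule for named genes were chosen before the data were examined. Named genes were, per comparison against scramble, the 10 largest rises and 10 largest falls among called genes whose groups did not overlap (10% of genes do so by chance with 3 against 3) and whose higher group mean reached the median of all tested genes. The same rule gave the 5 largest per direction between treatments, and up to 4 members of each list with the smallest p were taken. Of genes called the same way in all 3 comparisons against scramble, the 10 with the largest smallest change were named per direction. CPT1A, CPT1B, CPT1C, CPT2 and SRC were set to be read always, but the probe sets of CPT1B carry more than 1 symbol and gave no tested value.

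For overlaps between comparisons that share the scramble arrays, 100 simulations of unchanged groups with the same controls were run. Alternatives were no filter, a filter at the 25th percentile, the mean of a gene's probe sets, each probe set on its own, no probe sets of kinds that can cross-hybridise, quantile normalization again, centring each array on its median, eBayes with trend and robust, only the groups compared, array weights, a replicate block, a fold threshold of 2, and leaving out each array in turn. Chosen after seeing the data were leaving out the 4 arrays, 1 per group, that correlated least with their group, the actin control signal as a covariate, a factor learned from differences between replicate arrays as a covariate, and camera between treatments.

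The steps were tested on simulated data shaped like ETX against scramble with 12887 genes. Of 100 genes changed by 0.5 on the log2 scale 96 were recovered, of 100 changed by 1 all 100 were, and 10 calls fell among 12687 unchanged genes. With 1 of 30 lists shifted by 0.3, that list was found and 0 others were called. The simulated noise was independent between genes, so this does not test list calls where the genes of a list vary together.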

Results

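Gene expression was measured in MDA231 (MDA-MB-231), an established human cell line from a triple-negative breast cancer, on 12 single-colour oligonucleotide arrays in 4 groups of 3. The control group carried a scrambled short hairpin RNA (scramble). The second group carried the same construct and received ETX, an abbreviation the labels do not spell out, read here as etomoxir, an inhibitor of carnitine palmitoyltransferase 1 (CPT1). The other groups carried lentiviral hairpins against CPT1 (shCPT-1) or CPT2 (shCPT-2), the enzymes that pass long-chain fatty acids into mitochondria for beta-oxidation. The design asks how each alteration of beta-oxidation changes expression against scramble, and how the 4 groups differ. The dose and duration of ETX on the arrays are not given in the sources used here. Nothing in the labels says that the 3 arrays of a group came from separate cultures, so every p-value measures only the spread between these arrays, which may be technical. Array medians lay between 74.9 and 77.2 intensity units, and 12887 genes had a value above the array median on at least 3 arrays. Log2 fold changes carry the standard error (SE) of the fit, with n = 3 arrays per group, and that number limits their precision.

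The targeted genes were read first. CPT1A, the liver-type CPT1 isoform, had a log2 intensity of 9.78 ± 0.12 (SD, n = 3) in scramble and 8.19 ± 0.13 in shCPT-1, which is 3.02-fold lower (log2 change -1.59 ± 0.08 SE, limma adjusted p = 1.97e-08). Its 3 shCPT-1 arrays read 8.11, 8.1 and 8.34, all under the lowest scramble array at 9.64. ETX raised CPT1A 2.16-fold (1.11 ± 0.08, adjusted p = 1.46e-06). In shCPT-2 it was slightly lower (-0.23 ± 0.08, adjusted p = 0.0318), a call that ended when scramble 2, scramble 3, shCPT-2 1 or shCPT-2 3 was left out. CPT2 fell from 7.41 ± 0.09 in scramble to 6.41 ± 0.19 in shCPT-2, 2.0-fold lower (-1.0 ± 0.10, adjusted p = 5.46e-06), and its shCPT-2 arrays read 6.61, 6.22 and 6.39 against a lowest scramble value of 7.31. CPT2 was 0.22 ± 0.10 above scramble in shCPT-1, which did not pass (adjusted p = 0.0987). With ETX it was 0.27 ± 0.10 higher (adjusted p = 0.043), which ended when any scramble or ETX array, shCPT-1 2 or shCPT-2 3 was left out. CPT1C, the brain-type isoform, did not pass in any comparison against scramble (changes of -0.17, 0.08 and -0.07). CPT1B was not analysed here, because its probe sets carry more than 1 gene symbol. All kept probe sets of CPT1A and of CPT2 fell in the knockdown of their gene, by different amounts. Those of CPT1A changed by -1.594, -1.333 and -0.763 in shCPT-1 and by 1.113, 1.035 and 0.595 with ETX. The CPT1A sizes given above are thus the largest of its kept probe sets. Those of CPT2 changed by -1.001 and -1.272 in shCPT-2.

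**Figure D1:**
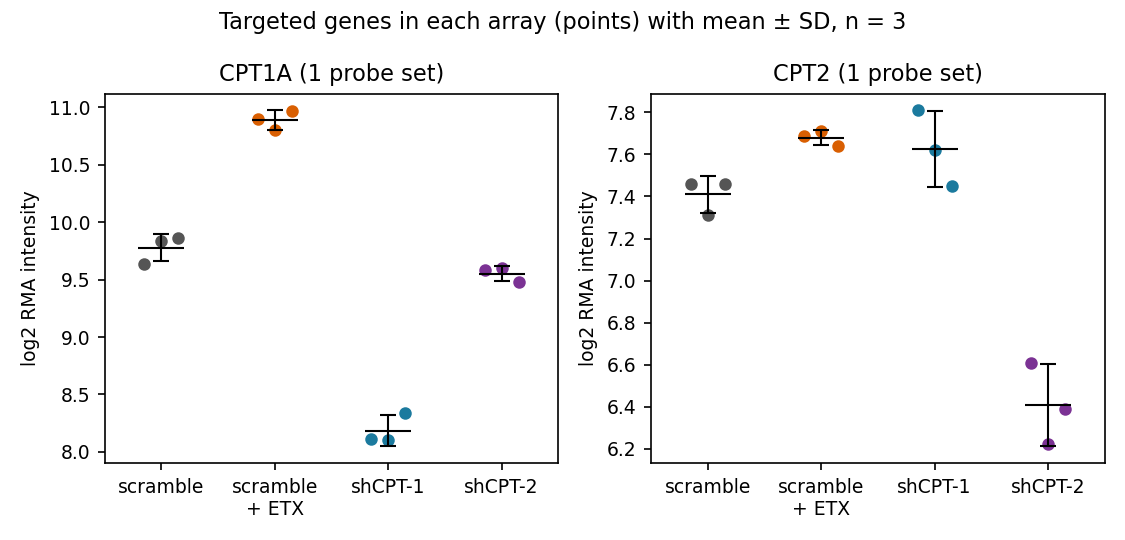
Log2 RMA intensity (vertical axis) of CPT1A and CPT2 in each array by group; points are arrays, the bar is the mean and the whiskers the SD of 3 arrays. CPT1A lies between 8.1 and 8.34 in shCPT-1 against 9.64 to 9.86 in scramble, and CPT2 between 6.22 and 6.61 in shCPT-2 against 7.31 to 7.46.

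Under the rule for named genes, the largest rise with ETX was that of PDK4, a kinase that restrains pyruvate dehydrogenase. It went from a log2 intensity of 5.02 ± 0.14 (SD), under the array medians, to 8.86 ± 0.26 (3.83 ± 0.17, adjusted p = 3.53e-08), so its fold rests on a low scramble signal. ANGPTL4, an inhibitor of lipoprotein lipase, rose 4.63-fold (2.21 ± 0.07) and PLIN2, a lipid droplet coat protein, 4.1-fold (2.04 ± 0.08). CTH, the cystathionine gamma-lyase of cysteine synthesis, rose 4.19-fold (2.07 ± 0.05), CHAC1, which breaks down glutathione, 3.24-fold, and ASNS, asparagine synthetase, 3.21-fold (1.68 ± 0.05). PTGS2, the inducible cyclooxygenase, rose 4.16-fold (2.06 ± 0.10) and IL1B, the cytokine interleukin-1 beta, 3.97-fold (1.99 ± 0.11). TMEM64 (1.80 ± 0.29) and SEL1L3 (1.68 ± 0.07) completed the 10 largest rises under that rule, and TMEM64 had a scramble SD of 0.57. The falls were smaller. PMEPA1, a negative regulator of TGF-beta signalling, fell 2.34-fold (-1.23 ± 0.05), HMGB3 2.06-fold and PLXNA1, PLAU, SLCO4A1, NEURL1B, SPDEF, CDC27, GAS2L1 and FAM20C between 1.79-fold and 1.94-fold. PLAU is the urokinase plasminogen activator. For CDC27, 2 other kept probe sets were called in the opposite direction.

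Of the 12887 genes, 2821 were higher and 2498 lower with ETX than in scramble (limma, Benjamini-Hochberg adjusted p under 0.05). The changes were mostly small, with a median absolute log2 change of 0.28 among called genes, and 56 genes rose and 3 fell by at least 2-fold. Scramble had a larger 3′ minus 5′ signal of the actin control probe sets (2.07 ± 0.27 SD log2 units) than ETX (1.75 ± 0.06), shCPT-1 (1.73 ± 0.23) or shCPT-2 (1.68 ± 0.23). That control measures RNA integrity or labelling. With it as a covariate, a choice made after seeing the data, 2167 genes were higher with ETX in place of 2821, and 1665 lower in place of 2498.

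Of 30 gene lists fixed beforehand, 9 were shifted against the other genes with ETX (camera with a preset correlation). The ATF4 stress response, the programme of amino acid supply and integrated stress, had 30 of 33 measured members higher and 0 lower, the same counts as when adjusted over the list alone (median 0.70, adjusted p = 8.26e-22). ASNS and CHAC1 belong to it, as do SLC7A11, the cystine importer (1.32 ± 0.05), and JDP2 (1.41 ± 0.07). The list of ER chaperones and unfolded protein response genes had 13 of 19 higher and 0 lower, also when adjusted over the list alone (median 0.33, adjusted p = 6.15e-06), with DNAJB9 at 1.09 ± 0.06 and the chaperone HSPA5 at 0.48 ± 0.05. Both calls held with an estimated correlation (adjusted p = 0.00096 and adjusted p = 0.0426). The NRF2 antioxidant list had 16 of 21 higher and 0 lower, the same adjusted over the list alone (median 0.43, adjusted p = 5.44e-08, adjusted p = 0.0817 with an estimated correlation). TXNRD1 (0.76 ± 0.04), GCLC (0.78 ± 0.07) and AKR1C1 (0.89 ± 0.07) were among them. SLC7A11 is on this list as well.

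Among PPAR target genes 6 of 14 were higher and 1 lower with ETX, or 6 and 2 adjusted over the list alone (median 0.14, upper quartile 1.19, adjusted p = 0.00346, adjusted p = 0.0597 with an estimated correlation). PDK4, ANGPTL4, PLIN2, CPT1A and the carnitine-acylcarnitine carrier SLC25A20 (1.22 ± 0.06) carried that list. Lysosome and autophagy genes had 12 of 28 higher and 2 lower, equal when adjusted over the list alone (adjusted p = 0.0106, adjusted p = 0.145 with an estimated correlation), with CTSL at 0.42 ± 0.06 and MAP1LC3B at 0.31 ± 0.04. Growth-factor immediate early and MAPK feedback genes had 12 of 21 higher and 4 lower, equal when adjusted over the list alone (adjusted p = 0.0249, adjusted p = 0.145 with an estimated correlation), with EREG at 1.65 ± 0.19, DUSP5 at 0.60 ± 0.06 and FOSL1 at -0.66 ± 0.07. Mitosis genes went down together, 28 of 36 lower and 2 higher, the same adjusted over the list alone (median -0.24, adjusted p = 4.13e-09, adjusted p = 0.0597 with an estimated correlation). KIF20A fell by 0.61 ± 0.05, CENPF by 0.43 ± 0.04 and CDC20 by 0.42 ± 0.04. DNA replication genes had 18 of 35 lower and 2 higher, the same adjusted over the list alone (adjusted p = 0.000192, adjusted p = 0.0597 with an estimated correlation), with LIG1 at -0.51 ± 0.05 and MCM5 at -0.46 ± 0.06. Cholesterol synthesis genes had 9 of 19 lower and 1 higher, or 9 and 2 adjusted over the list alone (adjusted p = 0.0106, adjusted p = 0.145 with an estimated correlation). LSS fell by 0.51 ± 0.06 and HMGCS1 by 0.43 ± 0.06. Without scramble replicate 3 that call ended (adjusted p = 0.0614).

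The other lists were not called with ETX. NF-kB cytokines and targets had 9 of 25 higher and 4 lower (adjusted p = 0.0534), with PTGS2, IL1B, IL6 (1.27 ± 0.06) and CXCL8 (0.72 ± 0.06) higher. That list passed when scramble 1, scramble 2, ETX 1, ETX 2 or shCPT-1 2 was left out, at a lowest adjusted p = 0.0247. It also passed with quantile normalization again (adjusted p = 0.0368), the mean of a gene's probe sets (0.0439), the actin covariate (0.0483) and a covariate learned from the differences between replicate arrays (the replicate factor, 0.0379). Both covariates were chosen after seeing the data. Beta-oxidation genes had 8 of 26 higher and 6 lower (adjusted p = 0.117), and ETFDH rose by 1.02 ± 0.09. Fatty acid synthesis had 3 of 21 higher and 7 lower (adjusted p = 0.0847), with FASN at -0.59 ± 0.05 and SREBF1 at -0.70 ± 0.07. With the replicate factor this list and glycolysis passed as lower (adjusted p = 0.0379 for each), and with the actin covariate as well (0.041 and 0.0481). Counts higher and lower were 9 and 0 of 27 for proteasome subunits (adjusted p = 0.0847, 0.0194 without scramble 3 and 0.026 without the 4 arrays that stood apart in their group), 6 and 1 of 18 for p53 targets, and 8 and 2 of 22 for YAP and TEAD targets. They were 3 and 7 of 21 for glycolysis, 3 and 6 of 21 for Src family kinases and partners, and 1 and 6 of 37 for cytoplasmic ribosomal proteins. They were 10 and 5 of 26 for invasion proteases and matrix receptors, 11 and 8 of 36 for interferon-stimulated genes, and 7 and 7 of 25 for hypoxia genes. They were 12 and 12 of 68 for oxidative phosphorylation subunits, 5 and 5 of 19 for the TCA cycle, and 3 and 4 of 15 for mitochondrial biogenesis. Epithelial genes had 3 and 4 of 18, and mesenchymal genes 6 and 6 of 23. Markers of other cell types had 1 and 2 of 9 (endothelium), 0 and 2 of 6 (fibroblasts), 1 and 2 of 7 (leukocytes) and 2 and 5 of 13 (luminal breast epithelium). SRC itself was 0.24 ± 0.10 lower with ETX, which did not pass (adjusted p = 0.0798), and its changes were 0.03 ± 0.10 in shCPT-1 and 0.07 ± 0.10 in shCPT-2.

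**Figure D2:**
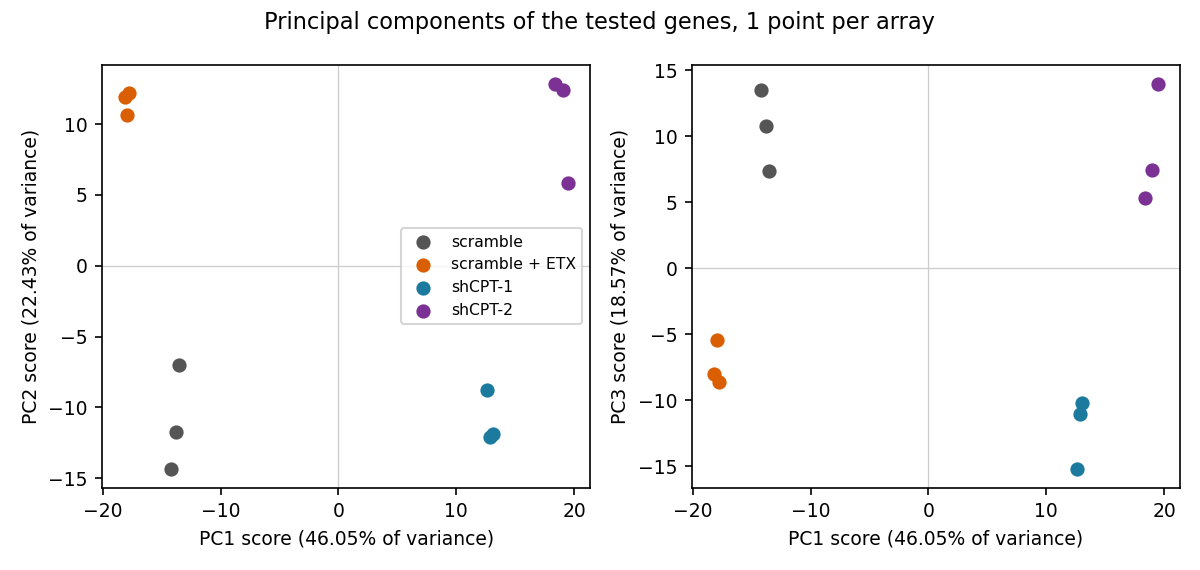
Scores of the 12 arrays (1 point each, coloured by group) on principal components 1, 2 and 3 of the tested genes. PC1, with 46.05% of the variance, puts all 6 scramble and ETX arrays between -18.15 and -13.53 and all 6 knockdown arrays between 12.58 and 19.45.

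The knockdown arrays stood apart from the scramble and ETX arrays. The correlation between arrays of a group was 0.9945 to 0.9989, above the highest value of 0.9913 between groups. In shCPT-1 against scramble, MATN2, a matrix protein, rose 3.59-fold (1.84 ± 0.08), SFTA3 3.46-fold (1.79 ± 0.06) and the long noncoding RNA AFAP1-AS1 3.24-fold (1.70 ± 0.10). EEF1A2, L1CAM, RANGRF, CTH, TRAPPC1, NKX2-1 and EREG rose between 2.56-fold and 2.88-fold. L1CAM is an adhesion molecule and NKX2-1 a transcription factor of lung and thyroid. The falls were larger: SRPX fell 11.9-fold (-3.58 ± 0.07, adjusted p = 1.27e-11), FAM133A 9.07-fold, FABP5, a fatty acid binding protein, 8.36-fold (-3.06 ± 0.05), and the phospholipase PLCB1 7.91-fold (-2.98 ± 0.12). OLFML3 and FAT3 fell 6.69-fold and 6.62-fold, and SVIP, SHISA2, EHF and KYNU between 3.66-fold and 4.49-fold. EHF is an epithelial ETS factor and KYNU the kynureninase of tryptophan breakdown. In all, 2979 genes were higher and 2323 lower, and 74 rose and 85 fell by at least 2-fold.

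In shCPT-1, 7 of the 30 lists were shifted with the preset correlation, and none held with an estimated correlation. The ATF4 list had 22 of 33 higher and 2 lower, or 23 and 2 adjusted over the list alone (median 0.37, adjusted p = 1.41e-06, adjusted p = 0.0538 with an estimated correlation), including GDF15 (1.15 ± 0.08), DDIT4 (1.15 ± 0.08) and ASNS (0.84 ± 0.05). Hypoxia response genes had 18 of 25 higher and 4 lower, equal when adjusted over the list alone (median 0.35, adjusted p = 0.000169, adjusted p = 0.122 with an estimated correlation). LOX, which crosslinks collagen, rose by 1.16 ± 0.04 and the mitophagy receptor BNIP3 by 0.90 ± 0.05, while ADM fell by 1.39 ± 0.06. NF-kB cytokines and targets had 13 of 25 lower and 2 higher, or 14 and 2 adjusted over the list alone (median -0.27, adjusted p = 0.000413, adjusted p = 0.146 with an estimated correlation). The chemokines CXCL3 and CXCL2 fell by 1.39 ± 0.06 and 1.02 ± 0.07, and NFKBIA by 0.60 ± 0.05. Cholesterol synthesis had 10 of 19 lower and 0 higher, or 12 and 1 adjusted over the list alone (adjusted p = 0.000812, adjusted p = 0.122 with an estimated correlation). HMGCS1 fell by 0.76 ± 0.06 and SC5D by 0.83 ± 0.07.

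Invasion proteases and matrix receptors had 14 of 26 higher and 3 lower in shCPT-1, or 16 and 3 adjusted over the list alone (median 0.30, adjusted p = 0.0111, adjusted p = 0.146 with an estimated correlation). The plasminogen activators PLAT and PLAU rose by 0.89 ± 0.06 and 0.60 ± 0.05, while the gelatinase MMP9 fell by 1.72 ± 0.10 and the collagenase MMP1 by 0.52 ± 0.04. DNA replication genes had 15 of 35 lower and 4 higher, equal when adjusted over the list alone (adjusted p = 0.0117, adjusted p = 0.191 with an estimated correlation), with POLA2 at -0.55 ± 0.05 and FEN1 at -0.50 ± 0.05. That list no longer passed without scramble replicate 3 (adjusted p = 0.0554) or without the 4 arrays that stood apart (0.0534). Immediate early and MAPK feedback genes had 10 of 21 higher and 4 lower, or 12 and 4 adjusted over the list alone, with DUSP5 at 1.18 ± 0.06 and IER3 at -0.47 ± 0.04. That last list was near the threshold (adjusted p = 0.0478, adjusted p = 0.23 with an estimated correlation), and it ended without scramble 1, scramble 3, shCPT-1 1 or shCPT-1 3. It also ended with the actin covariate (adjusted p = 0.0526), quantile normalization again (0.0687), the mean of a gene's probe sets (0.0791) and without the 4 arrays that stood apart (0.0534).

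Lists not called in shCPT-1 were, as counts higher and lower, beta-oxidation with 7 and 3 of 26, PPAR targets with 3 and 3 of 14, fatty acid synthesis with 6 and 5 of 21 and glycolysis with 5 and 0 of 21. The acyl-CoA dehydrogenase ACADSB (0.91 ± 0.12) and SREBF1 (1.09 ± 0.07), a regulator of lipid synthesis, were higher there, and the pantetheinase VNN1 was lower (-1.70 ± 0.14). Oxidative phosphorylation had 20 and 11 of 68, the TCA cycle 6 and 4 of 19, mitochondrial biogenesis 3 and 2 of 15, Src family kinases and partners 4 and 5 of 21, ER chaperones 6 and 6 of 19 and NRF2 genes 2 and 8 of 21. NRF2 genes passed as lower with the replicate factor (adjusted p = 0.0312) and the actin covariate (0.00946). Mitosis had 12 and 2 of 36, interferon-stimulated genes 16 and 10 of 36, mesenchymal genes 7 and 6 of 23, epithelial genes 7 and 3 of 18, YAP and TEAD targets 5 and 3 of 22 and p53 targets 4 and 4 of 18. Lysosome and autophagy genes had 14 and 5 of 28, ribosomal proteins 4 and 2 of 37, proteasome subunits 2 and 1 of 27, and markers of leukocytes 1 and 2 of 7, endothelium 1 and 4 of 9, fibroblasts 0 and 1 of 6 and luminal epithelium 4 and 3 of 13. Among the latter CLDN4, a tight junction protein, rose by 1.63 ± 0.15.

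In shCPT-2 against scramble, ZNF184, a zinc finger gene, rose 8.08-fold (3.02 ± 0.05, adjusted p = 2.68e-12) and ESM1, an endothelial proteoglycan also made by tumour cells, 5.42-fold (2.44 ± 0.07). AFAP1-AS1, SFTA3, MATN2, NKX2-1 and LCP1, an actin-bundling protein, rose between 3.58-fold and 4.68-fold, and MGC12916, CMTR2 and the protease ADAMTS1 between 2.81-fold and 3.18-fold. PLCB1 fell 14.7-fold (-3.88 ± 0.12), EHF 12.6-fold (-3.65 ± 0.06), SRPX 6.6-fold and FAM133A 6.36-fold. SLCO4A1, KYNU, MAGEA6, SHISA2, COXFA4L3 and VEGFA, the endothelial growth factor (-2.30 ± 0.11), fell between 4.36-fold and 6.15-fold. PLCB1 (5.85) and EHF (6.18) lay under the array medians in shCPT-2, so their folds there rest on a low signal. There were 3295 genes higher and 2642 lower, with 100 rising and 154 falling by at least 2-fold.

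In shCPT-2, 5 lists were shifted with the preset correlation, and none held with an estimated correlation. Hypoxia response genes had 14 of 25 lower and 3 higher, equal when adjusted over the list alone (median -0.23, adjusted p = 0.000742). VEGFA, DDIT4 (-1.76 ± 0.08) and the glycolysis regulator PFKFB4 (-1.30 ± 0.05) fell, and LOX rose by 1.16 ± 0.04. NF-kB cytokines and targets had 16 of 25 lower and 4 higher, equal when adjusted over the list alone (median -0.32, adjusted p = 0.00297), with IL11 at -1.37 ± 0.05, NFKBIA at -0.84 ± 0.05 and IL24 at 1.09 ± 0.08. The ATF4 list had 18 of 33 higher and 4 lower, or 19 and 4 adjusted over the list alone (median 0.24, adjusted p = 0.0161), with ASNS at 0.61 ± 0.05 and the amino acid importer SLC7A5 at 0.51 ± 0.05. Cholesterol synthesis had 9 of 19 lower and 0 higher, or 10 and 0 adjusted over the list alone (adjusted p = 0.0161), with HMGCS1 at -0.43 ± 0.06. Each of these 4 lists had an adjusted p = 0.278 with an estimated correlation. Interferon-stimulated genes had 16 of 36 lower and 6 higher, or 17 and 7 adjusted over the list alone (median -0.14, adjusted p = 0.0161, adjusted p = 0.288 with an estimated correlation). TRIM22 fell by 1.59 ± 0.07, SAMD9L by 1.28 ± 0.07 and IFITM1 by 1.24 ± 0.06. Cholesterol synthesis no longer passed without scramble replicate 3 (adjusted p = 0.0718), nor did interferon genes without shCPT-2 replicate 2 (adjusted p = 0.0561). Without the 4 arrays that stood apart in their group, a choice made after seeing the data, only the hypoxia list stayed past the threshold in shCPT-2.

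Lists not called in shCPT-2 were, as counts higher and lower, beta-oxidation with 7 and 9 of 26, PPAR targets with 2 and 7 of 14, fatty acid synthesis with 5 and 6 of 21 and glycolysis with 3 and 10 of 21. Glycolysis passed as lower with the replicate factor (adjusted p = 0.0423) and the actin covariate (0.0216). HADH, another beta-oxidation enzyme, fell by 0.52 ± 0.05. Oxidative phosphorylation had 17 and 19 of 68, the TCA cycle 8 and 7 of 19, mitochondrial biogenesis 9 and 2 of 15, Src family kinases and partners 3 and 7 of 21, ER chaperones 3 and 9 of 19 and NRF2 genes 5 and 7 of 21. The aldo-keto reductase AKR1C3, on the NRF2 list, fell by 1.89 ± 0.07. DNA replication had 13 and 5 of 35, mitosis 11 and 6 of 36, mesenchymal genes 4 and 6 of 23, epithelial genes 7 and 5 of 18, invasion proteases 8 and 6 of 26 and immediate early genes 6 and 9 of 21. YAP and TEAD targets had 11 and 3 of 22, p53 targets 8 and 3 of 18, lysosome and autophagy genes 12 and 5 of 28, ribosomal proteins 3 and 3 of 37 and proteasome subunits 7 and 2 of 27. Markers of leukocytes had 0 and 3 of 7, endothelium 2 and 3 of 9, fibroblasts 0 and 3 of 6 and luminal epithelium 2 and 6 of 13. The leukocyte markers lower in shCPT-2 were HLA-DRA (-1.75 ± 0.13), CD74 (-1.42 ± 0.07) and LAPTM5 (-1.09 ± 0.04), of which HLA-DRA and CD74 take part in antigen presentation. That list passed as lower with the actin covariate (adjusted p = 0.0176). Median, mean and test differed in sign only for lists that were not called.

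**Figure D3:**
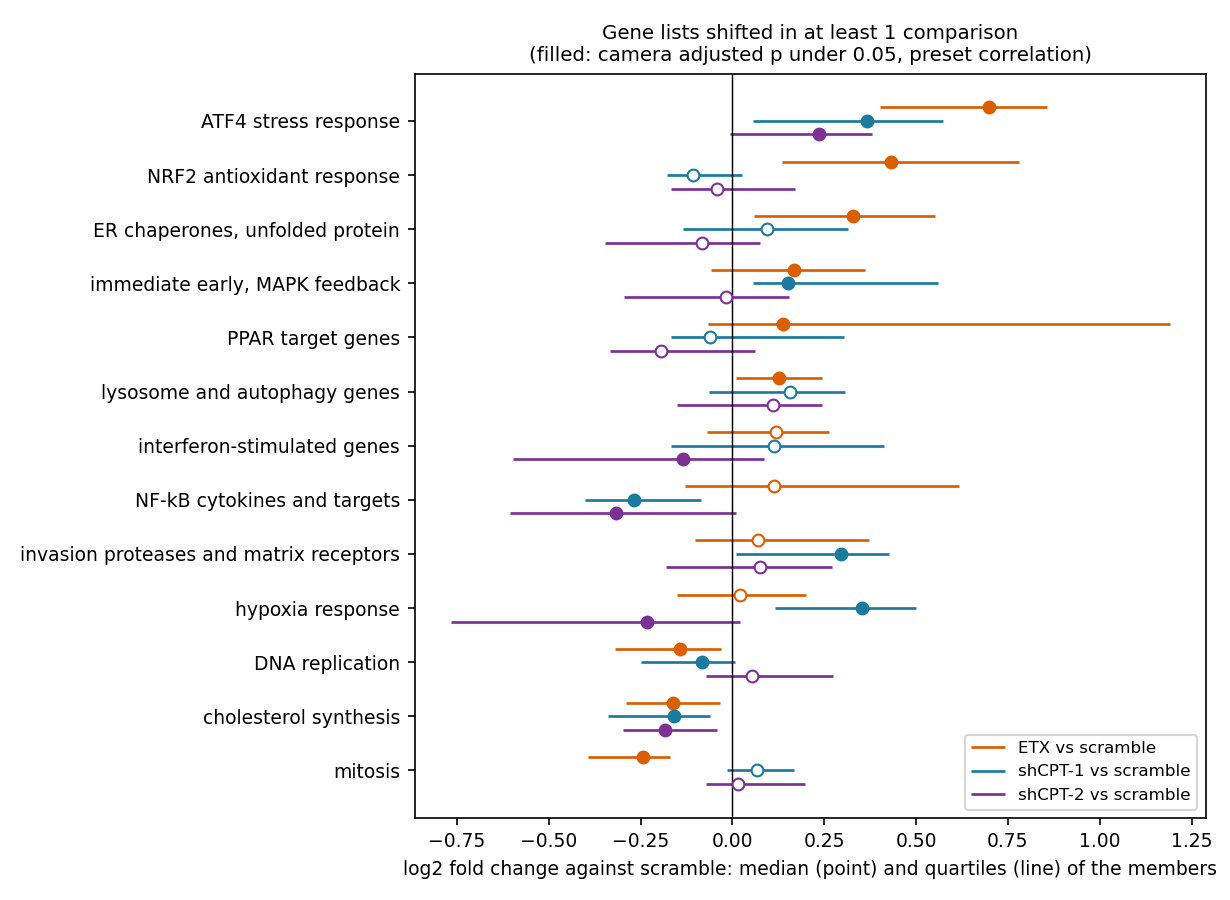
Median (point) and quartiles (line) of the log2 fold change against scramble over the measured members of each list shifted in at least 1 comparison; colours are comparisons and filled points mark an adjusted p under 0.05 with the preset correlation. The ATF4 list has medians of 0.70, 0.37 and 0.24 and hypoxia genes 0.35 and -0.23 in the knockdowns, and of these calls only that of ATF4 with ETX holds with an estimated correlation (adjusted p = 0.00096, against 0.0538 and 0.278 for ATF4 and 0.122 and 0.278 for hypoxia in the knockdowns).

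Some genes were called the same way in all 3 comparisons against scramble. There were 922 higher and 547 lower, where independent lists of those sizes would share 167 and 92, and unchanged groups simulated against the same controls shared 0.01 on average. Those groups gave almost no calls, so the simulated overlap sets no level for lists of this size. CTH rose by 2.07, 1.41 and 1.0 with ETX, shCPT-1 and shCPT-2, and KLF4, a stress-responsive transcription factor, by 1.48, 0.93 and 0.81. DUSP1, an early MAPK phosphatase, rose by 1.01, 0.94 and 1.27, and EREG, an EGF receptor ligand, by 1.65, 1.35 and 0.78. TMEM64, TAF1A, SIAH2, CMTR2, RAD51C and SELENOT were the other leading genes. MMP9 was 2.35-fold, 3.28-fold and 3.45-fold lower, and SPDEF, an ETS factor of luminal cells, fell by 0.90, 1.15 and 1.90. PMEPA1 fell by 1.23, 0.72 and 1.77 and SLCO4A1 by 0.94, 0.80 and 2.62, with PLPP3, ZBED6, ISM1, FBXO43, RASEF and PAK6 as the other leading falls. With the replicate factor, which moved with the actin control signal, ZBED6 was no longer called with ETX (-0.74 to -0.39, adjusted p = 0.0764). The ETX changes of SELENOT (0.74 to 0.35), RAD51C (0.74 to 0.42), SIAH2 (0.84 to 0.55), TMEM64 (1.80 to 1.23) and RASEF (-0.70 to -0.41) shrank but still passed. Without scramble replicate 1, 572 genes were higher and 334 lower in all 3. On its other kept probe set DUSP1 was -0.089, -0.126 and -0.157, and TMEM64 in shCPT-2, SELENOT with ETX and PLPP3 with ETX and in shCPT-1 also turned direction on another probe set. RASEF had 2 probe sets called in the opposite direction in each knockdown and 1 with ETX. The 3 scramble arrays cannot be split into sets of at least 2 arrays, so part of the excess may come from the shared controls.

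The knockdowns shared the most. Of the genes called in shCPT-1 and shCPT-2, 1833 were higher in both and 1397 lower in both (762 and 476 for independent lists), while ETX shared 1273 and 874 with shCPT-1 (652 and 450) and 1450 and 985 with shCPT-2 (721 and 512). The covariance of fold changes across genes was 0.07108 between the knockdowns, 0.02357 between ETX and shCPT-1 and 0.02977 between ETX and shCPT-2, where shared controls alone gave 0.00275, 0.00275 and 0.00276. Pearson's r across genes, which are not independent replicates, was 0.667, 0.296 and 0.334, against simulated values of 0.499, 0.498 and 0.5. The simulated groups held noise only, where a shared control group of equal size fixes r near 0.5. Those simulated values therefore set no level for r in groups that differ, and an r below them is no sign of a smaller overlap than shared controls give. The moderated F test over the 4 groups called 8989 genes (69.8% of those tested).

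Direct comparisons between treatments showed where they parted. PDK4 read 8.86 with ETX and lay under the array medians in both knockdowns, at 5.38 and 4.27. IL1B and ANGPTL4 were 8.19-fold and 6.69-fold lower in shCPT-2 than with ETX. SREBF1 was 3.46-fold and RCSD1 3.9-fold higher in shCPT-1 than with ETX. SRPX, PLCB1, FABP5 and FAT3 were 8.67-fold to 11.7-fold lower in shCPT-1 than with ETX, and AFAP1-AS1, MATN2 and EEF1A2 3.4-fold to 3.68-fold higher. In shCPT-2 against ETX, ZNF184, AFAP1-AS1, MATN2, SFTA3 and LINC02582 led the rises under the rule for named genes, at 3.42-fold to 6.51-fold. PLCB1 and EHF were 17.1-fold and 15.2-fold lower there. Counts were 2955 higher and 2550 lower for shCPT-1 against ETX, and 3203 and 2693 for shCPT-2 against ETX. Between the knockdowns, 2287 genes were higher and 2288 lower in shCPT-2 than in shCPT-1. ZNF184 was 9.14-fold, ESM1 4.16-fold, ADAMTS1 3.33-fold, FAT3 3.09-fold and ADAMTS6 2.91-fold higher in shCPT-2. In the other direction, PTGES, a prostaglandin E synthase, was 7.62-fold, DDIT4 7.51-fold, S100A4 5.75-fold, RASD1 4.59-fold and SLCO4A1-AS1 4.42-fold lower. SRC was 0.31 ± 0.10 higher in shCPT-2 than with ETX on the probe set with the highest mean (adjusted p = 0.0246). Its other kept probe set gave 0.003, and the mean of both did not pass (adjusted p = 0.0987). It was 0.27 ± 0.10 higher in shCPT-1 than with ETX, which did not (adjusted p = 0.0504).

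Camera on these contrasts was run after seeing the data. The ATF4 list was lower in shCPT-1 (median -0.33) and shCPT-2 (median -0.51) than with ETX, as were PPAR targets (-0.34 and -0.65) and ER chaperones (-0.26 and -0.38), and these calls held with an estimated correlation (highest adjusted p = 0.0471). The PPAR list includes CPT1A, the targeted gene of shCPT-1, so the fall of that member there may come from the hairpin itself. Mitosis genes were higher in shCPT-1 than with ETX, 29 of 36 (median 0.34), and NF-kB genes lower (median -0.33), each with an adjusted p = 0.0471 with an estimated correlation. In shCPT-2 mitosis genes were likewise higher, 28 of 36 (adjusted p = 0.055 with an estimated correlation). In shCPT-2 against shCPT-1, hypoxia genes (median -0.56, adjusted p = 0.0137 with an estimated correlation) and interferon-stimulated genes (median -0.27, adjusted p = 0.0405 with an estimated correlation) were lower. Immediate early genes (median -0.24) and luminal epithelial markers (median -0.35) were lower too, and DNA replication genes higher (median 0.17), at adjusted p = 0.0405, 0.0408 and 0.0408 with an estimated correlation.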

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

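Chosen only after the results were seen were the tests of the large changes shared by the knockdowns, of the ETX calls and of the replicate factor, and the count of hypoxia genes lower in shCPT-2. The hypoxia tests with the factor and with the mean of probe sets, and the splits of the arrays, were set before their results were seen.

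Some genes went opposite ways in a pair of treatments, each called in both comparisons against scramble and in the direct comparison. There were 655 such genes for ETX and shCPT-1, 659 for ETX and shCPT-2 and 358 for the knockdowns. Independent lists of those sizes would give 1086, 1217 and 1205, so these counts are no excess, and the shared scramble arrays also lower them. PTGES changed by 1.33 in shCPT-1 and -1.60 in shCPT-2, S100A4 by 1.33 and -1.20, DDIT4 by 1.15 and -1.76, and ADAMTS6 by -0.73 and 0.81.

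Hypoxia response genes differed between the knockdowns, with a median of -0.56 (-0.559) in shCPT-2 minus shCPT-1, and 20 of 25 members lower in shCPT-2. The mean factor scores of the knockdowns hardly differed (0.019 ± 6.991 SD in shCPT-1 and 0.583 ± 3.492 in shCPT-2). The factor as a covariate could therefore barely move this contrast. The upper quartile of the members was -0.344 with and without it, which by itself decides nothing. With the mean of a gene's probe sets that quartile was -0.161 and the median -0.559, so averaging over probe sets did not end the difference. That mean includes the chosen probe set and is the same for genes with 1 kept probe set. It therefore does not exclude the choice of probe set as a part of the difference. Culture conditions, such as density or oxygen at harvest, and the knocked down gene may each give this pattern. They cannot be told apart because each knocked down gene was read in 1 group, whose arrays may share a culture.

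Both knockdowns shared large changes, with 26 genes called the same way at 1.5 or more on the log2 scale, 7 higher and 19 lower. COL4A5, chosen after its values were seen, changed by -2.96 and -3.16, with an ETX value of 0.06, and lay under the array medians in both knockdowns. All 26 also passed the same way in both knockdowns against the ETX arrays, which argues against a chance deviation of the scramble arrays, and all 26 passed with the replicate factor as a covariate. Their median ETX change in the direction of the knockdowns was -0.039 (quartiles -0.212 and 0.122) against 2.13 in the knockdowns. ETX called 5 of the 26 the same way and 5 the opposite way, so ETX as given here did not reproduce these changes as a set. Its dose and duration are not known and the arrays do not measure beta-oxidation, so this does not decide on blocked beta-oxidation as their cause. Selection of different cells when the lines were made may explain the shared changes, as may a lasting effect of the knockdowns. These 2, and any other difference tied to the lines, cannot be told apart here because each predicts the small median absolute ETX change of 0.185.

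A factor learned from differences between replicate arrays followed the actin control within groups, with Pearson's r = -0.84 (exact permutation p = 0.0262) and Spearman's rho = -0.86 (exact permutation p = 0.0231) over 1296 arrangements of the 12 arrays. This was the 1 relation tested, and r was -0.72 without scramble 1 and 2, which is consistent with RNA quality as a source of the factor. With the factor as a covariate 3843 of 5319 ETX calls passed in the same direction (72.3%), as did 59 of 59 at 2-fold or more, which argues against the factor as the whole cause. For the other 1476 calls, which ended, the median absolute change went from 0.212 to 0.136 and the SE from 0.066 to 0.062. These calls were picked because they ended, so a fall relative to the SE follows from that choice.

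Probe sets without a single gene name, outside the comparisons by gene, also held signal. Of 5065 that were kept, 1203 were called for ETX against scramble, 1231 for shCPT-1 and 1376 for shCPT-2.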

How the results depend on the processing

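Leaving out the 4 arrays that stood apart, the actin covariate and the factor covariate were tests chosen only after the results were seen. Counts kept within 1.5 times of their value under no filter, the filter at the 25th percentile, the mean of probe sets, both normalizations, eBayes with trend, only the groups compared and the factor covariate. With ETX more genes were lower than higher with quantile normalization again (2676 higher, 2818 lower), with array weights (3800, 3994) and without the 4 arrays apart (3358, 3448), so the larger side changed in each. Each probe set on its own gave counts of probe sets, higher and lower, of 5098 and 3905 (ETX), 5044 and 3782 (shCPT-1), 5759 and 4494 (shCPT-2), 4588 and 4254 (shCPT-1 against ETX), 5060 and 4701 (shCPT-2 against ETX) and 3674 and 3772 (shCPT-2 against shCPT-1). The F test gave 15616, and all 3 comparisons 1606 and 891, because more units were tested. At 2-fold, counts were 56 and 3, 74 and 85, 100 and 154, 81 and 145, 63 and 206, and 33 and 88 in that order, with 369 in the F test and 1 and 1 in all 3, by the stricter threshold. Without probe sets that can cross-hybridise, 343 genes were lower in all 3, with fewer genes tested. For the following the cause was not tested. Array weights gave 3994, 3554 and 4093 genes lower against scramble, 3739 and 3730 between the knockdowns, and 1787 and 1295 in all 3. Without the 4 arrays apart, 1515 and 998 genes passed in all 3, and 1 list was shifted in shCPT-2. The scramble array left out there, scramble 3, had an actin 3′ minus 5′ signal of 1.764, while the kept scramble 1 and scramble 2 read 2.248 and 2.195. ETX arrays read 1.678, 1.784 and 1.778, so that choice widened the difference in this control between scramble and ETX. With the actin covariate 2167 genes were higher and 1665 lower with ETX, and 560 and 294 passed in all 3. With an estimated correlation 2, 0 and 0 lists were shifted, and fry gave 22, 22 and 24, as it does not compare a list with other genes. Leaving out 1 array moved genes higher in all 3 from 572 (without scramble 1) to 1212 (without scramble 3) and genes lower from 334 to 721. The other counts fitted again this way, genes higher or lower per comparison, the F test and lists shifted, moved by no more than 1.5 times. Overlaps of pairs and opposite calls were not fitted again.

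Replicate numbers did not pair the arrays: over 18 same-numbered pairs the correlation of deviations ran from -0.457 to 0.327, and 3 arrays correlated best with their own number. With the replicate block 2732 genes were higher and 2343 lower with ETX. Of 260 values of named genes (247 called) over the 26 alternatives that apply to single genes, 6675 gave a result and 85 had no probe set left without those that can cross-hybridise. The 260 values cover genes picked for the text, which are only a part of those the rule for named genes gave. Of the 6675, 6545 kept their side of the threshold, 88 no longer passed, 31 newly passed and 11 reversed, all on another probe set, with the cause not tested. A value that passed in neither fit counted as kept even where its sign turned. For each probe set on its own, this tally read only the probe set of a gene with the smallest absolute change, so it can miss reversals on the others. With ETX, 2 other probe sets of CDC27 and 1 of RASEF were called in the opposite direction and are not among the 11. On its other probe set DUSP1 was -0.089 with ETX, -0.126 in shCPT-1 and -0.157 in shCPT-2, SELENOT was -0.117 with ETX and TMEM64 was -0.051 in shCPT-2. PLPP3 was 0.239 with ETX and 0.028 in shCPT-1, also without probe sets that can cross-hybridise, and RASEF was 0.154 in shCPT-1 and 0.341 in shCPT-2. The number of arrays limits precision, and genes above the median on fewer than 3 arrays were not tested.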

Other observations

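The reading of the 2-fold ETX genes in the knockdowns and the actin covariate were chosen only after the results were seen, and the splits of the arrays were set before.

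Of the 59 genes changed by at least 2-fold with ETX, 34 were called the same way in shCPT-1 and 6 the opposite way, and 33 and 14 in shCPT-2. Over all 5319 ETX calls, 1273 were higher in both ETX and shCPT-1, 874 lower in both and 655 opposite, and 1450, 985 and 659 for shCPT-2. All of these comparisons share the scramble arrays, whose deviations push the changes the same way, so the counts alone do not measure a shared response. Across all genes the covariance with ETX was 0.02357 for shCPT-1 and 0.02977 for shCPT-2, where noise in the shared controls alone gave 0.00275 and 0.00276, so that noise does not account for the whole pattern. A difference in quality between the scramble arrays and the others was not part of that simulation. CTH, KLF4 and MMP9 were called the same way in all 3. ANGPTL4 rose by 2.21 with ETX and fell by 0.53 ± 0.07 in shCPT-2.

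Splits of the arrays were counted for each model result. For 3 arrays against 3 there are 10 splits, too few for a share under 0.05. The real split was the 1 with as many genes in each comparison: 5319 for ETX, 5302 for shCPT-1 and 5937 for shCPT-2 against scramble, 5505 and 5896 for the knockdowns against ETX, each with a highest other of 0, and 4575 between the knockdowns, with a highest other of 1. For gene lists, 1 split gave as many as the 9 of ETX (highest other 7), 3 as many as the 7 of shCPT-1 (highest other 8) and 5 as many as the 5 of shCPT-2 (highest other 9). Of 100 splits of the 12 arrays, 1 of them the real split, only the real split reached 8989 genes in the F test (highest other 3683). Single arrays were moved between groups. If the 3 arrays of a group are technical repeats, this does not exclude a chance difference between cultures. For genes higher in all 3 comparisons, 1 of 100 gave as many as 922 (highest other 526), and for genes lower, 2 of 100 gave as many as 547 (highest other 584), a share under 0.05 for both. These splits test only whether the groups differ, not whether calls are shared beyond the shared controls, and another split gave more genes lower than the real one. Without scramble 1 the real counts were 572 and 334, and with the actin covariate 560 and 294.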
